A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

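RNA-seq of polyadenylated RNA from 12 human organoid libraries and 6 mouse cortex libraries was used. Per the labels' protocols, total RNA was extracted with TRIzol, stranded libraries were made after oligo(dT) selection, and they were sequenced as read pairs on a NovaSeq instrument. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used with the build hg38, which the notes list for the mouse samples as well although the mouse table carries mouse gene IDs. The versions, the annotation, the strand setting and the choice of genes are not given in the sources used here. The deposited values are read as TPM, a unit inferred from the values, because library totals were nearly equal across groups and the decimals were rounded to 0.01. TPM keeps no depth, so no counting interval or detection floor is given.

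The human table used here held 15304 genes, of which 15289 had a symbol through the annotation, and 13 were not in GENCODE release 29. Its totals per library lie well below those of the mouse table, so it holds part of the genes over which the values were scaled, among them 12540 of 19951 protein-coding genes. Solute carrier (7 of 374) and cytochrome P450 (0 of 56) genes, for example, are largely not analysed here, and lists with such members have fewer tested genes than they name. The mouse table held 55414 gene IDs with 0 matched to a symbol, so gene lists were not run on it. Coordinates are those of GENCODE release 29 on GRCh38. All sample columns were used.

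Samples were grouped by genotype and day from their titles. The 12 organoid libraries entered 1 fit with 4 group means, from which the 2 knockout comparisons, their interaction and the day comparison of controls were taken, and the mouse libraries entered a separate fit. Genes with at least 1 TPM in at least 3 libraries were kept (10698 human and 14787 mouse genes). Values were taken as log2(TPM + 1), so a fold change is on that scale and understates the change of low genes. The unit was not known when the tests were fixed, and because it turned out to be TPM a test on the log scale replaced a count test. The test was limma (version 3.58.1, R 4.3.3) with trend and robust settings and Benjamini-Hochberg adjustment over genes, and a gene was called at adjusted p under 0.05. An adjusted p in the text is from limma unless camera or another test is named. With 3 libraries against 3, an exact permutation test cannot give a two-sided p under 0.1, so no test of single genes outside the model was run.

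Of 35 gene lists fixed before the data were examined, 32 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists within each comparison. No camera call held with an estimated correlation in any comparison. fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Named genes follow a rule fixed at the same time. It names CDYL (not analysed here), NNAT and a gene that is not reported here, then the 5 largest rises and 5 largest falls among called genes whose higher group mean is at least 10 TPM, whose libraries do not overlap between groups, and whose symbol is not a bare identifier, a readthrough or a mitochondrial gene. It then names the 2 to 4 members of each described list with the smallest adjusted p. Genes outside that rule, such as BLCAP, NECTIN3 and the markers given per library, were chosen after their values were seen. In the day comparison, the fold change of each named gene is also given minus the median of all genes.

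The fit was tested on simulated data with 100 genes changed by each of 2 sizes. At day 30 it recovered 60% of tested genes changed by 1 on the log2 scale and 93% of those changed by 2, with 6.13% of calls false among 10601 genes. At day 80 it recovered 70.7% and 96%, with 6.21% false among 10574 genes, and in the mouse fit 74.7% and 96.9%, with 4% false among 14496 genes. The simulated noise was independent between genes, with 1 SD per gene for all groups. Correlated genes and groups of unequal spread were not simulated, so these rates need not hold for the real libraries. Alternatives changed the limma settings, the scaling (median-ratio, quantile), the filter (none, 5 TPM), the pseudocount (0.1), the fold minimum (2-fold), the libraries in the fit, a replicate block and each replicate in turn.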

Results

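Polyadenylated RNA was measured in cortical organoids grown from H9, a human embryonic stem cell line, and in embryonic mouse cortex. The organoids were CDYL+/+ controls or CDYL−/− knockouts sampled at day 30 or day 80, which gave 4 groups with n = 3 libraries each. The mouse libraries came from whole cortex at E15.5 (embryonic stage) of floxed controls and of animals that also carried Emx1-Cre, a Cre driver active in the dorsal forebrain, again n = 3 each. The source labels name Emx1-Cre for all 3 knockouts. The genotype labels of knockout libraries 2 and 3 read Emx2-Cre and Emx3-Cre instead, and the 3 were treated as 1 group. CDYL is a chromodomain protein that takes part in gene repression, and the series title names forebrain identity and neuronatin (NNAT) as its subject. The values are TPM (transcript abundance scaled to a fixed total per library), so the read depth behind them is unknown. The human genes analysed here added up to between 543687 and 569043 TPM per library and the mouse genes to between 988085 and 992310 TPM. The labels do not say whether replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. The sample titles name no knockout clone, so other differences between the cell lines cannot be told apart from loss of CDYL. CDYL itself, the targeted gene, is not analysed here, so its level does not check the genotype labels.

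The day 30 comparison asks what loss of CDYL changed early in organoid growth. NNAT, an imprinted gene that encodes a small membrane protein of neurons and endocrine cells, rose from 3.64 ± 1.23 TPM in controls to 832 ± 188 TPM in knockouts (SD, n = 3), a log2 fold change of 7.49 ± 0.20 (SE, adjusted p = 7.81e-10). DBX1, a homeobox gene of progenitors in the middle of the neural tube, rose from 1.03 ± 0.467 to 167 ± 59.7 TPM (log2 fold change 6.33, adjusted p = 1.36e-05). NTN1, which encodes the axon guidance cue netrin, FGF8, a signal of the anterior neural ridge and of the midbrain–hindbrain boundary, and HES3, a repressor expressed at that boundary, had log2 fold changes of 3.52, 3.43 and 3.85 (adjusted p = 0.00312, 0.00113 and 0.0253). MIR9-1HG, a host gene of a neural microRNA, fell from 147 ± 41.4 to 4.39 ± 3.10 TPM, a log2 fold change of -4.97 (adjusted p = 2.32e-04).

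NNAT (ENSG00000053438) lies on chromosome 20 from 37521206 to 37523693 on GRCh38, inside the span of BLCAP (37492472 to 37527931) and on the opposite strand. The sources used here do not state whether counting used strand, so reads of the 2 genes could be mixed. BLCAP itself had 138 ± 9.82 TPM in controls and 91.6 ± 6.4 TPM in knockouts at day 30 and did not pass the test (log2 fold change -0.58, adjusted p = 0.0841). The other genes with the largest falls were NECTIN3-AS1 (log2 fold change -4.36, adjusted p = 1.75e-05), ZNF667-AS1 (-4.05, 1.21e-07), LCN9, a lipocalin gene (-3.79, 4.49e-05), and ZNF506, a zinc-finger gene (-3.47, 4.68e-07). Without strand, reads of NECTIN3-AS1 and ZNF667-AS1 cannot be told apart from those of the genes they oppose. NECTIN3 itself did not pass the test at day 30 (log2 fold change 0.08, adjusted p = 0.932).

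**Figure D1:**
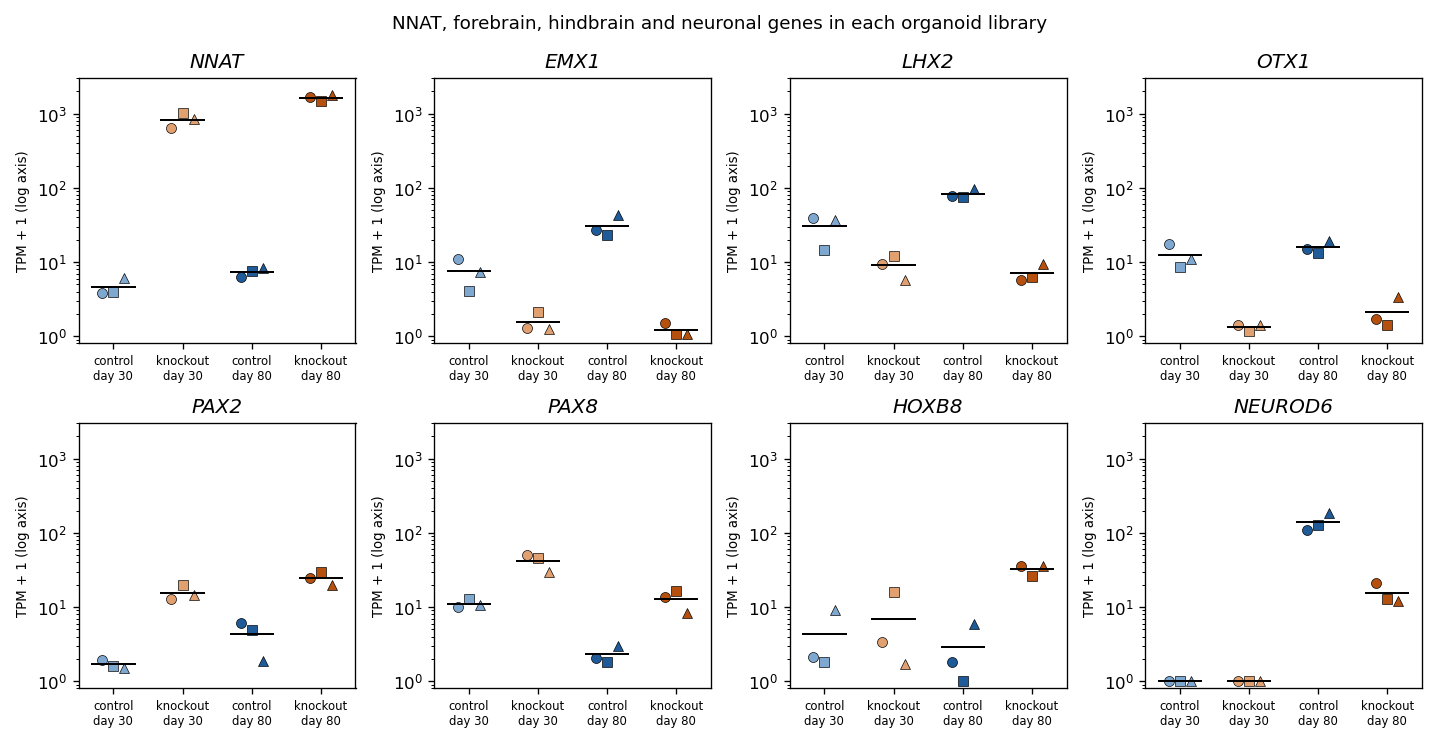
Each point is 1 organoid library (circle, square and triangle for replicates 1, 2 and 3), the horizontal line is the mean of 3 libraries, and the vertical axis is TPM + 1 on a log scale. NNAT lies between 640 and 1800 TPM in the 6 knockout libraries and between 2.85 and 7.45 TPM in the 6 control libraries, while NEUROD6 is listed at 0 in every day 30 library.

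Among 19 tested genes of telencephalon identity at day 30, 7 fell, 3 rose and 9 did not pass. Adjusted over the list alone, 10 fell and 5 rose. OTX1, a homeobox gene of the anterior brain, fell from 11.4 ± 4.54 to 0.34 ± 0.147 TPM (log2 fold change -3.15, adjusted p = 1.55e-04), and DMRT3 and EMX1, transcription factors of the dorsal telencephalon, had log2 fold changes of -1.87 and -2.20 (adjusted p = 0.00158 and 0.00356). FGF8 was among the 3 that rose. The list as a whole did not pass (camera, adjusted p = 0.0580). Of 38 tested genes that pattern the midbrain, hindbrain and spinal cord, 7 rose, 2 fell and 29 did not pass, and 9 rose and 3 fell adjusted over the list alone. The list ranked higher than other genes (camera, adjusted p = 0.00915), a call lost with adjusted p = 0.737 with an estimated correlation. It was also lost without knockout library 2 (adjusted p = 0.0523). PAX2, a gene of the midbrain–hindbrain boundary, rose from 0.69 ± 0.231 to 14.7 ± 3.54 TPM (log2 fold change 3.20, adjusted p = 2.78e-04), PAX8 rose to 41.0 ± 10.7 TPM (1.89, 0.00184) and EGR2, a hindbrain segment gene, rose by 1.82 on the log2 scale (0.00470), while ATOH1, a marker of the rhombic lip, fell from 12.1 ± 5.29 to 0.487 ± 0.435 TPM (-3.09, 4.17e-04).

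Of 9 tested retinoic acid response genes at day 30, 2 rose and 7 did not pass, and 4 rose adjusted over the list alone (camera, adjusted p = 0.00915, and adjusted p = 0.737 with an estimated correlation). CRABP1, a cellular retinoic acid binding protein, rose from 1230 ± 72.8 to 4348 ± 1078 TPM (log2 fold change 1.79, adjusted p = 6.07e-05), and HOXB1, a retinoic acid target of the hindbrain, rose by 2.67 on the log2 scale (0.0197), a call lost in 6 of 14 alternatives. CRABP2 and STRA6 had log2 fold changes of 1.48 and 1.25 and did not pass (0.0815 and 0.162). Of 12 tested diencephalon and eye genes, 2 rose and 2 fell both over all genes and adjusted over the list alone: POMC and SIX6 rose (log2 fold changes 2.97 and 1.37), while LHX9 and BARHL1 fell (-3.28 and -1.65; camera, adjusted p = 0.942). Of 10 tested genes of intermediate progenitors, 3 fell and 1 rose, and 3 fell and 2 rose adjusted over the list alone, with EOMES, NEUROG2 and HES6 lower (-2.22, -1.63 and -1.20) and PENK, an opioid precursor gene, higher (2.72; camera, adjusted p = 0.213). EOMES and HES6 lost their calls in 6 of 15 alternatives each. Of 14 tested cortical hem and choroid plexus genes, RSPO1 and RSPO2, activators of WNT signalling, fell (-1.73 and -2.47), BMP7 and CLIC6 rose (1.06 and 0.88) and 10 did not pass (camera, adjusted p = 0.153). CLIC6 lost its call in 7 of 13 alternatives. Adjusted over the list alone, 5 of the 14 fell and 2 rose. Control library 1 stood apart for AQP1 (13.7, 2.93 and 2.26 TPM in controls 1, 2 and 3) and BMP4 (12.2, 1.02 and 2.40 TPM). It did not for CLIC6 (0.35, 0.36 and 0.20 TPM). Among 8 tested SHH targets, PTCH1, the receptor gene that the pathway induces, rose (1.58, adjusted p = 0.00317) and GAS1 fell (-1.12, 0.00429), with the same 1 and 1 adjusted over the list alone (camera, adjusted p = 0.447).

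Of 18 tested imprinted genes at day 30, NNAT rose, PLAGL1, PEG10 and NDN fell (log2 fold changes -1.19, -1.95 and -0.50) and 14 did not pass. NDN lost its call in 10 of 15 alternatives (highest adjusted p = 0.700), and PLAGL1 and PEG10 in 1 each. Adjusted over the list alone, 3 rose and 5 fell. The list's median and mean were positive (0.04 and 0.26) while camera ranked it lower than other genes (adjusted p = 0.965). Genes of pluripotency also differed in level between the libraries. POU5F1 stood at 120, 6.85 and 69.9 TPM in knockout libraries 1, 2 and 3 at day 30, against at most 2.11 TPM in the 3 controls. None of the 11 tested pluripotency genes passed, nor did any adjusted over the list alone (LIN28A log2 fold change 4.43, adjusted p = 0.175, POU5F1 4.55, 0.230), although camera ranked the list higher (adjusted p = 0.0103, and adjusted p = 0.774 with an estimated correlation). That call was lost without knockout library 1 (adjusted p = 0.0747). LIN28A stood at 222, 114 and 105 TPM in knockout libraries 1, 2 and 3 of day 30 and at 13.9, 1.56 and 6.05 TPM in the controls. It passed in 1 of 15 alternatives. The fit shares 1 spread per gene over the 4 groups, and LIN28A stood at 0.05, 0.13 and 206 TPM in the day 80 controls. Not passing therefore does not show that LIN28A was alike in the day 30 groups.

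At day 30, limma called 623 of 10698 tested genes, 373 higher and 250 lower in knockouts, and 323 of them changed at least 2-fold. Leaving out control library 2 or 3, or knockout library 1, 2 or 3, gave 328, 340, 315, 370 or 386 calls, and a fit of only the 6 libraries compared gave 1329. HES3 lost its call in each fit that left out a library, while its log2 fold change stayed between 3.71 and 4.09 over all alternatives. Leaving out knockout libraries 1 and 3, those with the most POU5F1, kept 1 knockout library, with HES3 at 4.03. Of 36 named genes called, 14 held in every alternative.

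The day 80 comparison asks the same after longer growth. NNAT rose from 6.44 ± 1.05 TPM in controls to 1657 ± 149 TPM in knockouts (SD, n = 3), a log2 fold change of 7.81 ± 0.20 (SE, adjusted p = 4.81e-10). EMX1, a transcription factor of the dorsal telencephalon, fell from 30.0 ± 10.6 to 0.21 ± 0.251 TPM (log2 fold change -4.65, adjusted p = 1.62e-05), and EOMES, a marker of intermediate progenitors, fell from 32.3 ± 19.1 to 0.277 ± 0.136 TPM (-4.56, 2.74e-04). OTP, a homeobox gene of the hypothalamus, rose from 1.29 ± 0.735 to 75.1 ± 74.2 TPM (4.40, 0.00695). HOXB9 and HOXB8, genes of the posterior neural tube, rose by 3.92 and 3.88 on the log2 scale (0.0374 and 0.0130), and RPH3A, which encodes a synaptic vesicle protein, rose from 4.09 ± 1.27 to 51.2 ± 16.8 TPM (3.33, 3.82e-05). ZNF667-AS1 was again among the largest falls (-4.36, 5.21e-08). The muscle-type troponin genes TNNT2 and TNNC1 fell by 4.70 and 4.51 on the log2 scale (0.0267 and 0.0239), with TNNT2 at 287, 31.3 and 5.53 TPM in control libraries 1, 2 and 3 and at most 0.91 TPM in the 3 knockouts.

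Of 19 tested telencephalon genes at day 80, 13 fell, none rose and 6 did not pass, both over all genes and adjusted over the list alone (camera, adjusted p = 3.03e-08, and adjusted p = 0.569 with an estimated correlation). LHX2 fell from 82.1 ± 11.7 to 6.16 ± 2.06 TPM (log2 fold change -3.56, adjusted p = 1.51e-04), EMX2 from 37.3 ± 6.01 to 1.15 ± 1.04 TPM (-4.25, 1.77e-04) and OTX1 from 14.9 ± 2.99 to 1.14 ± 1.04 TPM (-2.98, 1.82e-04). Of 38 tested midbrain, hindbrain and spinal cord genes, 17 rose, none fell and 21 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 3.29e-06, and adjusted p = 0.230 with an estimated correlation). PAX8 rose from 1.29 ± 0.624 to 11.9 ± 4.16 TPM (2.46, 2.21e-04), and PAX2, PAX5 and IRX3, patterning genes of these regions, rose by 2.66, 1.83 and 1.90 on the log2 scale (6.77e-04, 0.00141 and 0.00151). Beside these groups, control library 3 held POU5F1 at 436 TPM, against at most 0.45 TPM in the other 2 controls and at most 0.23 TPM in the knockouts. It was the highest of the controls for 13 of the 19 telencephalon genes. Among the 38 patterning genes it was the lowest for 14, such as PAX2 (5.14, 3.92 and 0.88 TPM in controls 1, 2 and 3) and IRX3 (13.7, 23.7 and 7.19 TPM), and the highest for 18. Without it 12 telencephalon genes fell and 17 patterning genes rose.

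Neuronal groups moved in different directions at day 80. Of 10 tested genes of deep cortical layer neurons, 6 fell, none rose and 4 did not pass, and 7 fell adjusted over the list alone (camera, adjusted p = 1.28e-05, and adjusted p = 0.230 with an estimated correlation). NEUROD6 and NEUROD2, transcription factors of excitatory neurons, fell by 3.21 and 2.36 on the log2 scale (8.01e-06 and 3.42e-05), and BCL11B, a regulator of corticospinal neurons, and NFIB had log2 fold changes of -2.39 and -1.19 (5.52e-05 and 0.00270). Of 10 tested intermediate progenitor genes, EOMES, NEUROG2 and NEUROG1 fell (-4.56, -2.71 and -2.98), PENK rose (2.93) and 6 did not pass, with the same 3 and 1 adjusted over the list alone (camera, adjusted p = 0.239). Of 12 tested upper layer genes, 3 rose and 3 fell, and 6 rose and 3 fell adjusted over the list alone. CUX2 rose by 1.02 on the log2 scale, while MEF2C, PLXND1 and RORB had log2 fold changes of -2.10, -1.61 and -1.21 (camera, adjusted p = 0.688). The median of that list was 0.29, its mean -0.11 and its camera direction higher.

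Of 9 tested genes of the neuronal cytoskeleton and adhesion at day 80, 6 rose and none fell, and all 9 rose adjusted over the list alone (camera, adjusted p = 1.84e-04, and adjusted p = 0.569 with an estimated correlation). L1CAM, a neural adhesion molecule, rose from 128 ± 33.6 to 290 ± 25.6 TPM (log2 fold change 1.202, adjusted p = 0.00473), and MAPT, which encodes tau, STMN2 and STMN1 rose by 1.03, 1.07 and 0.43 on the log2 scale (0.0118, 0.0244 and 0.0188). Of 13 tested synapse genes, 6 rose and none fell, and 7 rose adjusted over the list alone (camera, adjusted p = 0.00427, and adjusted p = 0.632 with an estimated correlation), with SYN2, SYN1, CAMK2B and SYT1 at log2 fold changes of 1.04, 1.13, 0.77 and 0.76. Of 9 tested Cajal–Retzius genes, 5 rose and none fell, and 7 rose adjusted over the list alone (camera, adjusted p = 0.00712, and adjusted p = 0.569 with an estimated correlation). The members that moved included EBF2, EBF1, LHX1 and LHX5 (1.57, 1.34, 2.38 and 2.17), transcription factors that other neurons of the brainstem and spinal cord also use. Of 14 tested interneuron and ventral telencephalon genes, 4 rose and none fell, and 5 rose adjusted over the list alone (camera, adjusted p = 0.0363, and adjusted p = 0.569 with an estimated correlation), with SP9, GSX1, EBF1 and ERBB4 at 2.05, 1.90, 1.34 and 1.30. The camera call on this list was lost without control library 2 or knockout library 2 or 3 (highest adjusted p = 0.174). Control library 3 was the lowest of the controls for 7 of the 9 cytoskeleton genes, 9 of the 13 synapse genes, 7 of the 9 Cajal–Retzius genes and 5 of the 14 interneuron genes. Without it 3, 4, 2 and 3 genes of these lists rose, in place of 6, 6, 5 and 4. STMN2 stood at 563, 642 and 389 TPM and LHX5 at 9.99, 8.74 and 2.01 TPM in controls 1, 2 and 3. ERBB4 lost its call in 10 of 14 alternatives and EBF1, which also belongs to the Cajal–Retzius list, in 6 of 14. Without control library 3 they stood at 0.81 and 0.84 and did not pass.

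**Figure D2:**
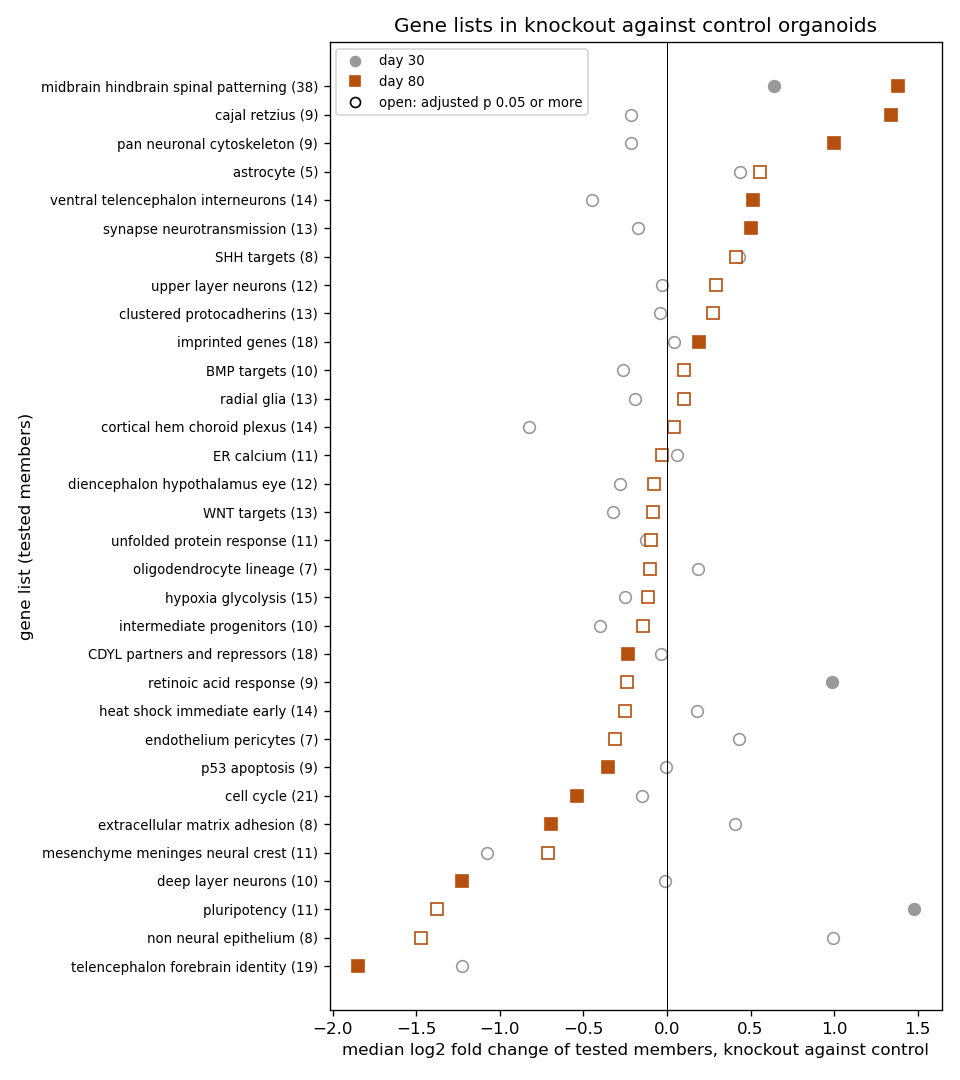
Each row is a gene list with its number of tested members, and the horizontal axis is the median log2 fold change of knockout against control organoids, with circles for day 30 and squares for day 80. Filled symbols are the 3 lists at day 30 and the 12 at day 80 with camera adjusted p under 0.05 at the preset correlation, none of which pass with an estimated correlation.

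Of 21 tested cell cycle genes at day 80, NUSAP1 and MCM3 fell (log2 fold changes -0.94 and -0.74), none rose and 19 did not pass, and 9 fell adjusted over the list alone (camera, adjusted p = 3.43e-04, and adjusted p = 0.796 with an estimated correlation). CCNB2 and UBE2C stood at -0.74 and -0.56 and did not pass (0.0567 and 0.0670). Control library 3, the library with POU5F1 at 436 TPM, was the highest of the controls for MCM3 (42.9, 40.9 and 90.3 TPM in controls 1, 2 and 3), NUSAP1 (50.3, 40.9 and 74.6 TPM) and CCNB2 (35.6, 31.3 and 74.4 TPM). It was the highest of the controls for 20 of the 21 genes, and without it the list's median moved from -0.54 to -0.20. Without it MCM3, NUSAP1, CCNB2 and UBE2C stood at -0.38, -0.71, -0.37 and -0.27. MCM3 kept its call there but lost it in 9 of 14 alternatives. Of 18 tested genes for CDYL partners and other repressors, 5 fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone (camera, adjusted p = 0.00678, and adjusted p = 0.569 with an estimated correlation). RCOR2, EZH2, REST and HDAC1 fell by 0.86, 0.52, 0.79 and 0.64 on the log2 scale. Control library 3 was the highest control for all 4, with HDAC1 at 50.6, 48.0 and 86.1 TPM in controls 1, 2 and 3. Without it HDAC1 stood at -0.38 and kept its call, and REST lost its call in 5 of 14 alternatives. Leaving out control library 3 left 3 of the 18 that fell and none that rose. Among 18 tested imprinted genes, 4 rose and 1 fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.0251, and adjusted p = 0.681 with an estimated correlation). Besides NNAT, the genes NDN, MAGEL2 and NAP1L5 rose by 0.62, 0.82 and 0.77. The camera call on imprinted genes was lost without control library 3 or knockout library 2 (highest adjusted p = 0.143). Of 9 tested p53 and apoptosis genes, BAX and CCNG1 fell (-0.51 and -0.56) and 7 did not pass, and 3 fell adjusted over the list alone (camera, adjusted p = 0.0199, and adjusted p = 0.569 with an estimated correlation). BAX and CCNG1 each lost their call in 8 of 14 alternatives, and without knockout library 2 BAX stood at -0.33 and did not pass. Without control library 3 none of the 9 passed. SESN1 and PMAIP1 stood at -0.35 and -0.66 and did not pass. The camera call was lost without control library 2 or knockout library 2 (highest adjusted p = 0.0746). Of 8 tested matrix and adhesion genes, TIMP1 and FBN2 fell (-0.76 and -0.63) and 6 did not pass, and 3 fell adjusted over the list alone (camera, adjusted p = 0.0251, and adjusted p = 0.569 with an estimated correlation). That call was lost without control library 3 or knockout library 1 (highest adjusted p = 0.0920). FBN2 lost its own call in 7 of 14 alternatives, and 1 of the 8 genes fell without control library 3.

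At day 80, limma called 1942 of 10698 genes, 1128 higher and 814 lower, of which 630 changed at least 2-fold. Leaving out knockout library 2 gave 1086 calls. A fit of only the 6 libraries compared gave 741, with 494 higher and 247 lower, and 15 of the 57 named calls were lost. The 1942 calls rest on 1 spread per gene shared with the day 30 groups. With each day fitted alone, day 30 had more calls (1329) than day 80 (741). The numbers of calls therefore do not show that day 80 had more effects. TNNT2 and HOXB9 lost their calls without any 1 library except control library 3, and TNNC1 without control library 2 or any knockout library (highest adjusted p over all alternatives 0.0720, 0.107 and 0.0940). Of 57 named genes called, 34 held in every alternative.

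**Figure D3:**
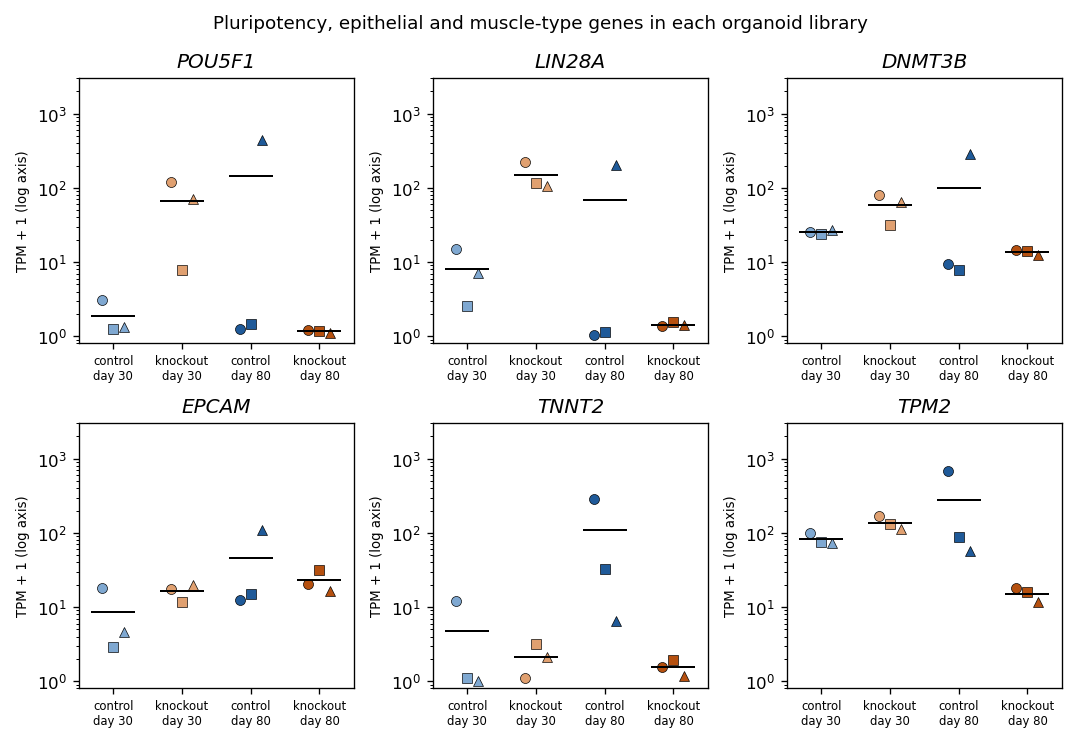
Each point is 1 organoid library (circle, square and triangle for replicates 1, 2 and 3), the line is the mean of 3 libraries, and the vertical axis is TPM + 1 on a log scale. Control library 3 at day 80 stands out for POU5F1 (436 TPM), LIN28A (206 TPM), DNMT3B (286 TPM) and EPCAM (109 TPM), and control library 1 at day 80 for TNNT2 (287 TPM) and TPM2 (690 TPM).

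Both days shared 161 genes higher and 63 genes lower in knockouts. Independent lists of those sizes would share 39.3 and 19.02, and the one-sided Fisher exact test gave p = 3.22e-62 and p = 4.98e-18. Genes are not independent replicates, so these p-values describe the overlap only. A further 64 genes passed at both days in opposite directions. The number that independent lists would give was not worked out for them, so 64 is not read as an excess. NNAT, DBX1, EMX1, OTX1, PAX2 and ZNF667-AS1 were among the named genes with the same direction at both days. Across all 10698 genes, the fold changes of the 2 days had a Pearson r of 0.142 and a Spearman rho of -0.0157. The 2 comparisons used different libraries.

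**Figure D4:**
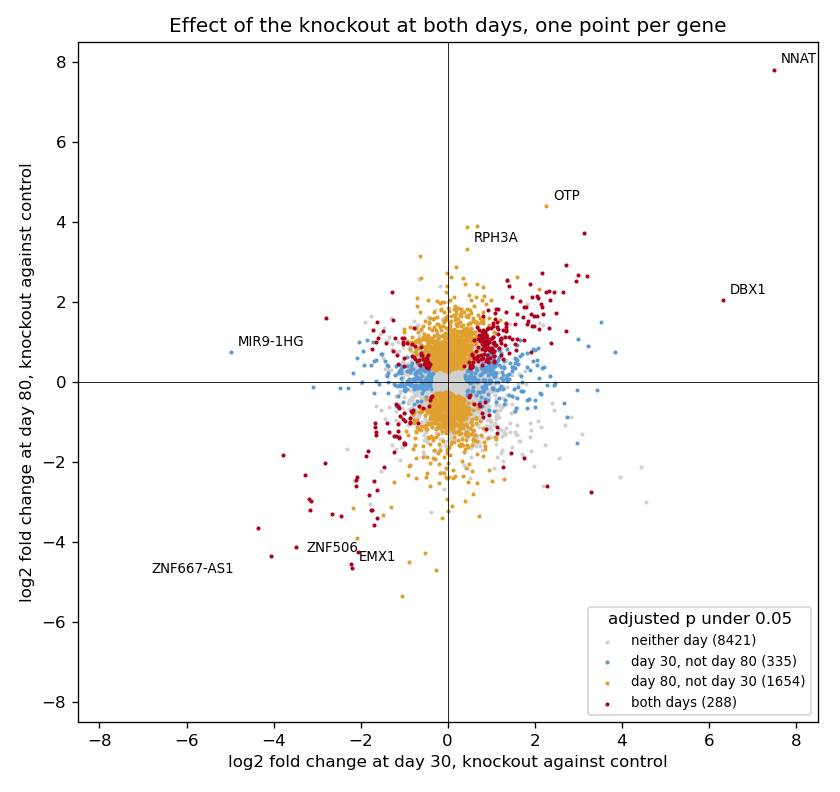
Each point is 1 of 10698 genes, with the log2 fold change of knockout against control at day 30 on the horizontal axis and at day 80 on the vertical axis. Colours mark adjusted p under 0.05 at day 30 and not day 80 (335 genes), at day 80 and not day 30 (1654) or at both (288), and NNAT lies at 7.49 and 7.81.

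The interaction of genotype with day asks which knockout effects differed between the days, and a gene is said to have risen where its knockout effect was more positive at day 80. MIR9-1HG had the largest rise (log2 difference 5.72, SE 0.70, adjusted p = 0.00279): it stood at 147 and 4.39 TPM in controls and knockouts at day 30, and at 1191 and 1918 TPM at day 80. MAB21L1, PRAME, TRH, which encodes thyrotropin-releasing hormone, and FZD10, a WNT receptor gene, had differences of 4.39, 3.80, 3.53 and 3.40. FZD10 lost its call in 7 of 20 alternatives. NMRK2, SFRP1, a secreted WNT antagonist, BST2, an interferon-induced gene, DBX1 and TPM2 had differences of -6.03, -4.89, -4.49, -4.28 and -4.07. NMRK2 stood at 54.1, 10.9 and 66.2 TPM in knockout libraries 1, 2 and 3 of day 30 and at 4.89, 3.03 and 41.6 TPM in the day 80 controls. Its high values were in the libraries with the most POU5F1. Leaving out knockout libraries 1 and 3 of day 30 together kept 1 knockout library at that day and ended 31 of the 37 named calls. NMRK2 and BST2 then stood at -4.46 and -3.70, and SFRP1, DBX1 and TPM2 at -5.12, -4.76 and -4.03, against -4.89, -4.28 and -4.07 with all libraries. TPM2 stood at 690, 88.3 and 56.1 TPM in the day 80 controls and its difference at -2.98 without control library 1 of day 80, where it kept its call. It lost the call in 9 of 20 alternatives and BST2 in 4 of 20. SFRP1 was higher in knockouts at day 30 (39.8 ± 19.5 against 181 ± 30.1 TPM) and lower at day 80 (145 ± 82.9 against 22.2 ± 11.8 TPM). The difference for NNAT was 0.31 and did not pass (adjusted p = 0.501).

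Of 19 telencephalon genes tested for the interaction, 6 fell and none rose, and 8 fell adjusted over the list alone (camera, adjusted p = 1.56e-04, and adjusted p = 0.667 with an estimated correlation), with SFRP1, FGF8, SP8 and EMX1 at -4.89, -3.62, -1.55 and -2.45. Of the 19, 4 fell without control library 3 of day 80. FGF8 stood at 0.643 and 0.367 TPM in controls and knockouts at day 80, so its difference mainly reflects day 30. Of 10 deep layer genes, 4 fell and none rose, and 6 fell adjusted over the list alone (camera, adjusted p = 1.18e-04, and adjusted p = 0.545 with an estimated correlation), with NEUROD6, NEUROD2, BCL11B and SOX5 at -3.21, -2.40, -1.66 and -1.56. NEUROD6 was listed at 0 in every day 30 library, so its difference is its day 80 effect alone. BCL11B stood at no more than 0.94 TPM in any day 30 library, and its difference at -0.48 without passing with a pseudocount of 0.1. Of 9 neuronal cytoskeleton and adhesion genes, 4 rose and 8 rose adjusted over the list alone (camera, adjusted p = 5.54e-05, and adjusted p = 0.667 with an estimated correlation), with STMN1, MAPT, GAP43 and STMN2 at 1.05, 1.79, 2.14 and 1.58. STMN2 and GAP43 lost their calls in 8 and 5 of 20 alternatives. Of 13 synapse genes, 4 rose and 6 rose adjusted over the list alone (camera, adjusted p = 0.0144, and adjusted p = 0.667 with an estimated correlation), with SYN2, CAMK2B, SYP and SYT1 at 1.03, 1.01, 1.40 and 0.97. These 4 genes lost their calls in 12, 11, 12 and 14 of 20 alternatives. None of the 13 passed without control library 3 of day 80, and the camera call was lost without knockout library 2 of day 80 (adjusted p = 0.0526). Of 9 Cajal–Retzius genes, EBF2 and EBF1 rose (2.82 and 1.96) and 3 rose adjusted over the list alone (camera, adjusted p = 0.0178, and adjusted p = 0.667 with an estimated correlation). Of 14 interneuron and ventral telencephalon genes, ERBB4, GSX1, SP9 and EBF1 rose (3.01, 2.61, 1.27 and 1.96), also 4 adjusted over the list alone (camera, adjusted p = 0.0427, and adjusted p = 0.667 with an estimated correlation). SP9 and EBF1 lost their calls in 14 of 20 alternatives each, and ERBB4 and GSX1 in 1 each. The camera call was lost without control library 3 or knockout library 1 of day 30, and without control library 2 or knockout library 2 or 3 of day 80 (highest adjusted p = 0.116).

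Of 18 CDYL partners and repressors tested for the interaction, WIZ rose (0.64), REST and HDAC1 fell (-1.31 and -1.02) and 15 did not pass, with 1 and 3 adjusted over the list alone (camera, adjusted p = 0.0342, and adjusted p = 0.667 with an estimated correlation). HDAC1 lost its call in 8 of 20 alternatives, and WIZ and REST in 3 each. Of 8 matrix and adhesion genes, FBN2 and TIMP1 fell (-1.13 and -0.86), and 5 fell adjusted over the list alone (camera, adjusted p = 0.00715, and adjusted p = 0.667 with an estimated correlation). TIMP1 and FBN2 lost their calls in 14 and 7 of 20 alternatives, and 1 of the 8 genes fell without control library 3 of day 80. Of 14 heat shock and immediate early genes, HSPB1 and HSPA1A fell (-1.12 and -1.17), and 4 fell adjusted over the list alone (camera, adjusted p = 0.0427, and adjusted p = 0.667 with an estimated correlation). Both genes lost their calls in 9 of 20 alternatives. Camera also ranked lower the lists of pluripotency (11 genes, adjusted p = 0.00135, and adjusted p = 0.667 with an estimated correlation) and non-neural epithelium (8 genes, adjusted p = 0.0305, and adjusted p = 0.723 with an estimated correlation). None of their genes passed, nor did any adjusted over the list alone. The call on CDYL partners was lost without control library 1 of day 30 or control or knockout library 3 of day 80 (highest adjusted p = 0.0748). That on non-neural epithelium was lost without control library 3 of day 30, or control library 3 or knockout library 1 of day 80 (0.121). That on heat shock genes was lost without control library 2 or 3 or knockout library 3 of day 30, or control or knockout library 1 or 2 of day 80 (0.118). POU5F1 and CLDN6 stood at -7.55 and -4.80, with POU5F1 at 436 TPM in control library 3 of day 80 and at 120 and 69.9 TPM in knockout libraries 1 and 3 of day 30. Without control library 3 of day 80 they stood at -4.77 and -2.79, and POU5F1 then passed.

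For the interaction, limma called 944 genes, 571 higher and 373 lower. Leaving out control library 2 or 3 of day 30, knockout library 1, 2 or 3 of day 30, control library 2 of day 80 or knockout library 2 of day 80 gave 386, 425, 429, 608, 623, 1501 or 524 calls, and leaving out knockout libraries 1 and 3 of day 30 together gave 33. Of 37 named genes called, 6 held in every alternative.

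The comparison of control organoids at day 80 with day 30 describes how they differed between the days without the knockout. Growth cannot be told apart from a harvest, culture or library batch that went with day. The median gene was 0.47 higher on the log2 scale at day 80 as deposited, a shift that median-ratio scaling brought to 0.02 and quantile normalization to -0.05, so fold changes in the following sentences are given relative to that median. NEUROD6, listed at 0 in the 3 day 30 controls, stood at 108, 128 and 184 TPM at day 80, and OASL, an interferon-induced gene that was also listed at 0, at 354, 440 and 103 TPM. IFIT2, CXCL10 and CCL5, genes of the interferon response or of chemokine signalling, rose by 7.11, 6.56 and 6.55 relative to the median (adjusted p before that subtraction 1.35e-09, 2.62e-07 and 4.13e-09). RSPO1, ATOH1, OLIG3, FGF17 and PGAM2 fell, with relative values of -3.78, -3.74, -3.67, -3.50 and -3.09. ATOH1 and OLIG3 mark dorsal progenitors of the hindbrain and spinal cord, and FGF17 is a signal of the anterior brain and midbrain–hindbrain boundary. NNAT stood at a relative value of 0.23 and lost its call with median-ratio scaling (adjusted p = 0.251).

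Of 21 tested cell cycle genes, 18 fell at day 80 and none rose, also adjusted over the list alone, and 20 fell with median-ratio scaling (camera, adjusted p = 1.63e-16, and adjusted p = 0.283 with an estimated correlation). MCM2, TYMS, UBE2C and PCNA had relative values of -1.95, -1.77, -2.13 and -1.68. All 10 tested deep layer genes rose, also adjusted over the list alone, and 8 with median-ratio scaling (camera, adjusted p = 6.81e-04, and adjusted p = 0.241 with an estimated correlation), with NEUROD2, NFIB and BCL11B at 5.37, 4.25 and 2.97. All 13 tested synapse genes rose, also adjusted over the list alone and with median-ratio scaling (camera, adjusted p = 5.16e-04, and adjusted p = 0.410 with an estimated correlation), with CAMK2B, SYN2, SYN1 and NLGN1 at 2.39, 1.90, 1.97 and 1.32. Of 5 tested astrocyte genes, GFAP, CLU, SPARCL1 and S100B rose (6.15, 1.98, 4.03 and 2.89), also 4 adjusted over the list alone and with median-ratio scaling (camera, adjusted p = 0.0821).

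Of 38 midbrain, hindbrain and spinal cord genes, 10 fell and 3 rose with day, and 8 fell and 3 rose adjusted over the list alone (camera, adjusted p = 1.25e-08, and adjusted p = 0.0984 with an estimated correlation), with PAX8, IRX3 and TLX3 at relative values of -2.77, -2.02 and -2.76. With median-ratio scaling 11 fell and 1 rose, and with quantile normalization 11 fell and none rose. Leaving out control library 3 of day 80 gave 14 that fell and 2 that rose. Of 12 diencephalon and eye genes, 4 fell and 2 rose, also adjusted over the list alone (camera, adjusted p = 0.00166, and adjusted p = 0.0984 with an estimated correlation), with BARHL1 and POMC at -2.39 and -2.28. Median-ratio scaling gave 5 that fell and 1 that rose. Of 14 cortical hem and choroid plexus genes, 5 fell and 3 rose, also adjusted over the list alone (camera, adjusted p = 0.00553, and adjusted p = 0.410 with an estimated correlation), with GDF7 and RSPO3 at -2.20 and -1.72 and BMP7 at 0.75. With that scaling 5 fell and 2 rose, and 5 fell and 1 rose without control library 3 of day 80. Of 11 mesenchyme, meninges and neural crest genes, TWIST1, TFAP2A and TFAP2B fell (-2.94, -1.05 and -2.02), 1 adjusted over the list alone (camera, adjusted p = 0.00184, and adjusted p = 0.181 with an estimated correlation), and 5 fell with median-ratio scaling. TFAP2B and TFAP2A lost their calls in 6 and 3 of 14 alternatives, and 2 of the 11 genes fell without control library 3 of day 80. Without that library TFAP2B moved from -1.55 to -0.80 before the median was subtracted and did not pass.

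Of 15 hypoxia and glycolysis genes, 13 rose and 1 fell with day, also adjusted over the list alone, and 9 rose and 1 fell with median-ratio scaling (camera, adjusted p = 0.0161, and adjusted p = 0.558 with an estimated correlation), with VEGFA, CA9, PGK1 and EGLN3 at relative values of 1.54, 1.93, 0.62 and 2.34. Of 11 genes of the unfolded protein response, 9 rose, also adjusted over the list alone, and 8 rose and 1 fell with median-ratio scaling (camera, adjusted p = 0.00677, and adjusted p = 0.410 with an estimated correlation), with SESN2, ATF5, TRIB3 and XBP1 at 1.22, 1.93, 2.01 and 1.08. All 11 genes of endoplasmic reticulum calcium handling rose, also adjusted over the list alone, and 7 with median-ratio scaling (camera, adjusted p = 0.0209, and adjusted p = 0.410 with an estimated correlation), with STIM2, CALR, CANX and ORAI1 at 0.93, 0.45, 0.71 and 0.52. Of 18 CDYL partners and repressors, 4 rose and 4 fell, 3 and 4 adjusted over the list alone, while median-ratio scaling left 13 that fell and none that rose (camera, lower, adjusted p = 0.00769, and adjusted p = 0.410 with an estimated correlation). EZH2 and RBBP7 stood at -1.26 and -0.82, and SUZ12 and MIER1, at 0.24 and 0.22, lost their calls with that scaling. Without control library 3 of day 80, 2 of the 18 rose and 8 fell. The list's median was -0.02 and its mean 0.02 before the median of all genes was subtracted. Of 13 WNT targets, 2 rose and 3 fell, with 1 that fell adjusted over the list alone (camera, lower, adjusted p = 0.0209, and adjusted p = 0.284 with an estimated correlation), against a median of 0.04 and a mean of 0.22 of the opposite sign. AXIN2, NKD1 and CCND1 stood at -1.07, -1.02 and -1.09. CCND1 and NKD1 lost their calls in 7 and 4 of 14 alternatives. Before the median was subtracted, CCND1 moved from -0.62 to -0.36 without control library 1 of day 80 and did not pass, and to -0.95 without control library 3 of day 80, where it passed. Median-ratio scaling left 4 WNT targets that fell and none that rose, and quantile normalization 6 and none. The camera call was lost without control library 1 of day 30 (adjusted p = 0.113). Without control library 3 of day 80, 1 of the 13 rose and 2 fell.

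Of 10698 genes, limma called 6380 with day, 5464 higher and 916 lower (85.6% higher). The share of calls that were higher was 50.6% with median-ratio scaling and 44.9% with quantile normalization, so the balance of directions is set by the scaling.

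The mouse comparison asks what loss of Cdyl in the dorsal forebrain changed in embryonic cortex. The files do not pair the mouse gene IDs with names, so the genes cannot be described by function, and Cdyl and Nnat are not analysed here. ENSMUSG00000073067 rose from 0.817 ± 0.586 TPM in controls to 65.4 ± 15.4 TPM in knockouts (SD, n = 3; log2 fold change 5.21, adjusted p = 1.19e-04). ENSMUSG00000096729 was listed at 0 in the 3 controls and stood at 31.7, 25.7 and 37.3 TPM in the knockouts (adjusted p = 1.58e-05). ENSMUSG00002075164 fell from 23.3 ± 8.75 to 5.17 ± 3.72 TPM (log2 fold change -2.07, adjusted p = 0.0445) and ENSMUSG00000119831 from 11.8 ± 2.22 to 3.44 ± 1.33 TPM (-1.56, 0.0299). Of 14787 tested genes, limma called 986, 461 higher and 525 lower in knockouts, of which 105 changed at least 2-fold. Leaving out control library 1 or 3, or knockout library 1, 2 or 3, gave 18, 55, 57, 9 or 166 calls, limma without its trend and robust settings gave 86, and no filter gave 56. Both falls lost their call in part of the 13 alternatives (8 and 7 of them). The groups did not overlap for 35.8% of genes, where chance gives 10% for any single gene. Genes move together within libraries, so the share over all genes can lie away from 10% without a group effect.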

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

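The tests on control library 3 of day 80 and on ribosomal protein genes were chosen after their results were seen. The effect of the knockout differed between day 30 and day 80 for 944 genes by the interaction term of limma. Of 100 drawn relabellings of genotype within days, the real one included, only the real 1 reached that number and the highest of the others gave 243. The others all mixed knockouts with controls on at least 1 day, which puts the genotype difference into the spread and lowers the calls. The draw therefore argues against labels with no relation to expression, and does not test the interaction itself. With 3 libraries against 3, 10 splits cannot give a share under 0.05. In each of those comparisons 1 split, the real one, reached the real number of calls, which was 623 at day 30, 1942 at day 80, 6380 for control organoids by day and 986 in mouse cortex, and the highest of the other splits gave 0, 1, 0 and 10.

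Among gene lists, the interaction passed with camera for telencephalon identity (adjusted p = 1.56e-04), deep layer neurons (1.18e-04), Cajal–Retzius cells (0.0178), ventral telencephalon and interneurons (0.0427), neuronal cytoskeleton (5.54e-05), synapse (0.0144), non-neural epithelium (0.0305), pluripotency (0.00135), CDYL partners and repressors (0.0342), heat shock and immediate early genes (0.0427) and matrix and adhesion (0.00715), and none of these held with an estimated correlation.

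Of the named genes, 55 had a knockout effect that differed between the days, and 29 of them had a more positive effect at day 80. Part of the 55 had been named by the size of this same difference. A gene near 0 TPM in both genotypes on 1 day shows only its effect on the other day. At day 80, ATOH1 stood at 0.353 and 0.187 TPM in controls and knockouts, and BARHL1 at no more than 0.10 TPM in any library. The log2 differences were 5.72 for MIR9-1HG, 4.39 for MAB21L1, 3.80 for PRAME, 3.53 for TRH, 3.40 for FZD10, 3.01 for ERBB4, 2.98 for ATOH1, 2.88 for RPH3A, 2.82 for EBF2 and 2.73 for PEG10. They were 2.61 for GSX1, 2.56 for RSPO1, 2.31 for RSPO2, 2.14 for GAP43, 1.98 for LCN9, 1.96 for EBF1, 1.79 for MAPT, 1.69 for BARHL1, 1.58 for STMN2 and 1.49 for CUX2. Smaller positive differences were 1.40 for SYP, 1.27 for SP9, 1.203 for MAGEL2, 1.12 for NDN, 1.05 for STMN1, 1.03 for SYN2, 1.01 for CAMK2B, 0.97 for SYT1 and 0.64 for WIZ.

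The other 26 had a more negative effect at day 80. The log2 differences were -6.03 for NMRK2, -4.89 for SFRP1, -4.49 for BST2, -4.28 for DBX1, -4.07 for TPM2, -3.62 for FGF8, -3.39 for NEUROG1, -3.21 for NEUROD6, -3.18 for HOXB1 and -3.16 for POMC. They were -2.60 for STRA6, -2.47 for PLXND1, -2.45 for EMX1, -2.40 for NEUROD2, -2.27 for EGR2, -1.87 for LHX2, -1.66 for BCL11B, -1.56 for SOX5 and -1.55 for SP8. Smaller ones were -1.31 for REST, -1.19 for SIX6, -1.17 for HSPA1A, -1.13 for FBN2, -1.12 for HSPB1, -1.02 for HDAC1 and -0.86 for TIMP1. NEUROD6 was listed at 0 in every day 30 library, so its difference is its day 80 effect alone. At day 80, FGF8 stood at 0.643 and 0.367 TPM in controls and knockouts, and HOXB1 at no more than 2.05 TPM in any library. The differences of FGF8 and HOXB1 mainly reflect day 30.

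Control library 3 of day 80 stood apart, with a mean correlation of 0.927 with its group against 0.954 and 0.951 for control libraries 1 and 2. A knockout library under a control label is excluded by NNAT, which stood at 7.45 TPM in it and at 1503 TPM or more in the day 80 knockouts. Of 11 pluripotency genes, 10 lay at least 4-fold above both other day 80 controls, as did all 8 genes of non-neural epithelium, against 155 of 10698 tested genes (1.45%). Cells of another type, such as undifferentiated stem cells, may therefore be present in this library, with POU5F1 at 436 TPM and DNMT3B at 286 TPM among their abundant genes. Slower maturation alone would not give these levels, since 10 of the 11 pluripotency genes also lay at least 4-fold above the highest day 30 control. POU5F1 stood at no more than 2.11 TPM there. These genes cannot decide whether the rest of the library was also less mature. The library was the highest day 80 control for 20 of 21 cell cycle genes and the lowest for 9 of 13 synapse genes. No other biological explanation was tested.

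More genes were higher than lower with day in control organoids, with a median log2 change of 0.47. Ribosomal protein genes took between 30.7% and 31.3% of the summed TPM of the genes analysed here in day 30 controls. In day 80 controls they took between 12.3% and 17.9%. Such a shift raises other genes on a scale of fixed totals. With the 58 ribosomal protein genes removed and libraries rescaled, the median was 0.21 and 68.5% of 5331 calls were higher. Those shares had been seen before the test. Removing genes whose share shrank and rescaling must lower the other genes, so the direction of this fall was fixed in advance. The values give the part of the shift that goes with the smaller ribosomal share and do not test its cause. The difference in age between the groups, or a batch that went with day, stays open for the rest.

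Zinc-finger genes were frequent among the genes that fell on both days: 11 of 63, where 2.86 would be drawn by chance (one-sided Fisher exact p = 1.08e-04), against 6 of 161 shared rises, where 7.30 would be drawn. This class was not among the 35 lists fixed before the data were examined, so the p-value only describes the overlap. The 11 were ZNF506, ZFP28, ZNF229, ZNF528, ZNF677, ZNF880, ZNF311, ZNF354C, ZNF841, ZNF471 and ZNF439, of which 9 lie on chromosome 19. Loss of whole 1 Mb stretches at most of these places is argued against. The 203 other tested genes within 1 Mb on chromosome 19 had a median log2 change of -0.048 at day 30 (quartiles -0.19 and 0.13). Genes that fell on both days were left out of the 203 and all places were pooled, so smaller losses at single places stay open. Whether reads moved to other zinc-finger genes cannot be told apart from noise, because the summed TPM of those genes differed by -120.3 with a standard error of 221, while the 11 genes lost 94.8 TPM. A change in how these genes are repressed without CDYL stays open and was not tested, as does another difference between the cell lines.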

How the results depend on the processing

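Leaving out knockout libraries 1 and 3 of day 30 together, and counting list members without control library 3 of day 80, were chosen after seeing the data. Alternatives on mouse sex genes, on CDYL or Cdyl, on Nnat and on human against mouse fold changes had been fixed before and were not run, because the mouse IDs are not paired with names or the target is not analysed here. TPM keeps no depth, so how precision differs between libraries is unknown. Of 3512 alternative values of named genes, 3085 stayed on their side of the threshold, 396 lost their call, 30 gained it and 1 changed sign: NNAT with day in controls, at -0.0025 with quantile normalization. Calls that held in every alternative numbered 14 of 36 named genes at day 30, 34 of 57 at day 80, 6 of 37 for the interaction, 48 of 60 for day and 2 of 4 in mouse.

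A fold minimum of 2 left 323 calls at day 30, 630 at day 80, 556 for the interaction, 2506 for day and 105 in mouse, and 109 of 224 shared calls, since it only removes calls. Only the 6 libraries compared gave 1329 calls at day 30 and 741 at day 80. In mouse, limma without trend and robust settings gave 86 and no filter 56. Without knockout libraries 1 and 3 of day 30 there were 103 calls at day 30 and 33 for the interaction, with the lone library assumed to vary like the other groups. Leaving out 1 library gave from 315 to 483 calls at day 30, 1086 to 2409 at day 80, 386 to 1501 for the interaction, 5481 to 6589 for day and 9 (without knockout library 2) to 1002 (without control library 2) in mouse, 156 to 264 shared calls, and 3 to 7 lists at day 30 (3 with all libraries). With an estimated correlation 0 lists passed in each comparison, and with fry 1 at day 30, 10 at day 80, 1 for the interaction and 14 for day, against 3, 12, 11 and 12 with camera. Fewer samples would not raise the calls at day 30 to 1329. The fit of all 12 organoid libraries shares 1 spread per gene over the 4 groups, which were not equally spread. Mean correlations with the own group were 0.927 to 0.954 in day 80 controls and 0.974 to 0.985 in the day 30 groups. A shared spread can then be too small for day 80 and too large for day 30. Beyond this and fewer samples or calls, no cause was examined.

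Replicate numbers were not used to pair the samples. Same-numbered libraries correlated between -0.165 and 0.0456 in their deviations from group means, and other pairs between -0.180 and 0.212. No sign of pairing was seen, but 3 libraries per group cannot exclude it. With a replicate block, 73 mouse genes were called in place of 986, and 530, 1725, 772 and 6218 genes at day 30, at day 80, for the interaction and for day.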

Other observations

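The tests on HOX and interferon genes were chosen after their results were seen. HOX genes mark positions along the hindbrain and spinal cord. Of 27 tested HOX genes, many of which also belong to the patterning list, 14 rose at day 80 with limma, none fell and 25 had a positive log2 fold change (median 1.65). HOXB8 stood at 34.9, 25.5 and 34.6 TPM in the knockouts and at 0.82, 0 and 4.86 TPM in controls 1, 2 and 3. HOXB5, HOXA6 and HOXC8 rose by 2.47, 1.65 and 2.13 on the log2 scale (adjusted p = 0.00415, 0.00845 and 0.0146). With median-ratio scaling 10 of the 27 rose and with quantile normalization 12, and with each none fell and 25 were positive (medians 1.49 and 1.47). At day 30, HOXA2 and HOXB1 rose (2.08 and 2.67, adjusted p = 0.00695 and 0.0197), and 20 of 27 were positive. Each scaling also gave 2 that rose, and HOXB1 lost its call in 6 of 14 alternatives. Control library 3 and knockout library 2 of day 30 stood highest in their groups for many HOX genes. HOXB9 was at 5.27, 4.92 and 31.1 TPM in controls 1, 2 and 3 and at 14.6, 64.5 and 3.66 TPM in knockouts. HOXB8 was at 1.15, 0.82 and 8.16 TPM and at 2.35, 14.8 and 0.73 TPM. HOX genes thus moved together within libraries, so the counts of positive genes at day 30 and in the interaction do not count separate effects. In the interaction, none rose and HOXB1 fell, while 20 of 27 were positive (median 1.31, and 1.14 and 1.25 with the 2 scalings). HOXB1 stood at no more than 2.05 TPM in any day 80 library, so its difference mainly reflects day 30.

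Clustered protocadherins, adhesion molecules that give neurons their surface identity, moved in both directions at day 80: of 13 tested genes, 4 rose and 1 fell, also adjusted over the list alone. PCDHB10, PCDHB2 and PCDHB9 rose (log2 fold changes 1.22, 0.96 and 0.87) and PCDHB5 fell (-1.005), and camera did not pass (adjusted p = 0.0886). Of 13 radial glia genes, NOTCH2, GLI3 and NOTCH3 fell (-0.85, -0.71 and -0.54) and HES5 rose (0.85), also 3 and 1 adjusted over the list alone (camera, adjusted p = 0.961).

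Interferon-response genes were among the largest rises with day in controls, and a hypothesis is that they rise with day in both genotypes. Of 25 tested members of a list written for this test, 25 rose in controls and 24 in knockouts, with median log2 changes of 5.21 and 3.81 (0.47 for all genes in controls), which is consistent with a rise that does not need CDYL. ISG15 went from 21.0 to 2203 TPM in controls and from 91.9 to 1455 TPM in knockouts. BST2 was the member that did not pass in knockouts (0.79, adjusted p = 0.337). At day 80, 6 of the 25 were lower in knockouts and none higher (median -0.59), and 5 passed the interaction: HERC6, IFIT1, USP18, ISG15 and BST2. What raised these genes was not tested.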
